A study of Homo sapiens with 24 samples.

How the data were processed

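RNA abundance was measured in HCT116 colon cancer cells and A375 melanoma cells after 24 h with vehicle (DMSO) or with 0.1 µM DS07551382, in the parent line and in a PTDSS2 knockout clone of each line. There were 8 groups of 3 libraries, 24 libraries in all, with 1 knockout clone per line. Per the labels' protocols, poly(A) RNA was selected and libraries were prepared with an NEBNext Ultra RNA kit. The labels do not say whether the replicates were separate cultures, so p-values measure only the spread between these libraries, which may be technical.

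Reads were aligned with STAR 2.4.2a and quantified with RSEM 1.2.23 on the human build hg19, per the submitters' processing notes. The annotation release, the strand setting and any filter are not given in the sources used here. The deposited expected counts are RSEM estimates per gene, per the file headers, which need not be whole because reads that match several genes are shared out. The deposited TPM values and the deposited FPKM values, per the file headers, are scaled for gene length and library size. TPM served only as an alternative for PTDSS2, and FPKM was not used. Each library listed 25343 genes by numeric identifier, and 25220 of them were matched to a symbol in a RefSeq gene table of assembly GRCh38.p14, used for names only. The 123 genes without a match held at most 0.0724% of the counts of a library. Coordinates are not given, because the gene table is of another build than the files.

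Expected counts were rounded to whole numbers. Libraries were scaled with TMM factors and genes were kept with edgeR's default expression filter (minimum count 10, minimum total 15). Each line was fitted over its 12 libraries with edgeR 4.0.16 in R 4.3.3, with a mean for each of its 4 groups. The quasi-likelihood F test with robust dispersion was two-sided, and p-values were adjusted by the Benjamini-Hochberg method over the genes tested. Genes with adjusted p under 0.05 are said to have risen or fallen. The comparisons were inhibitor against vehicle in the parent and in the knockout, knockout against parent in vehicle, and the inhibitor effect in the knockout minus that in the parent. A fit of all 24 libraries compared the inhibitor effect between the A375 and HCT116 knockouts. The standard error of a log2 fold change was its size divided by the square root of the F statistic.

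Gene lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01 between genes, adjusted over the lists of a comparison. The groups, comparisons, tests, gene lists and the rule for named genes were fixed before the data were examined. Of 29 lists, 28 were tested, and the list of mitochondrially encoded genes had no member among the genes analysed here. The rule named PTDSS1, PTDSS2 and PISD, the 8 largest rises and the 8 largest falls of a comparison, and up to 4 members of each list with the smallest adjusted p. The largest changes needed adjusted p under 0.05, a mean of at least 8 CPM and, between a pair of groups, libraries that did not overlap. Symbols of unnamed loci, small RNAs and antisense genes were skipped, and some genes that the rule named are not reported here. For the response shared by the knockouts the rule took the 10 genes up and the 10 down in both lines with the largest smaller change. Marker genes of the cell of origin were taken from the lists.

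The tests were tested on simulated data with counts drawn from the real gene means, dispersions and library sizes. At each fold 49 or 50 genes per line were changed, besides the members of 1 shifted list. The real inhibitor comparisons called 36.58% of genes in the HCT116 knockout and 37.41% in the A375 knockout, so recovery there may differ. For the inhibitor in the HCT116 knockout, over 13033 genes, edgeR recovered 50.0% of genes changed 1.25-fold, 77.6% at 1.5-fold, 86.0% at 2-fold and 100.0% at 4-fold, with 8 false calls among 181. For the A375 knockout, over 13343 genes, it recovered 52.0%, 90.0%, 86.0% and 95.9%, with 11 false calls among 180. For the effect in the HCT116 knockout minus that in the parent it recovered 30.0%, 63.3%, 76.0% and 94.0%, and for that in A375 36.0%, 74.0%, 76.0% and 91.8%. The differences of effects had 9 false calls among 149 in HCT116 and 9 among 151 in A375. Where nothing had been changed, edgeR made 0 calls for the inhibitor in the parents of both lines and for genotype in A375, and 2 false calls for genotype in HCT116. Camera called the list shifted by a simulated log2 change of 0.3 in both lines and 0 of 27 unshifted lists. Genes were drawn independently and lists were random, so this cannot show how often camera calls lists of correlated genes.

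Alternatives were DESeq2 size factors, library size alone, no filter, a filter at a mean of 5 CPM, DESeq2 1.42.0, limma-voom, only the 6 libraries compared, all 24 libraries, a replicate block, and each library left out in turn. For lists, an estimated correlation and the fry test were also run. Removal of trends with GC content and gene length, and thinning to the smallest library of a line, were added after seeing the data. Library pairs within a group were compared by a chi-square test of their counts, and no pair was identical (chi-square per degree of freedom 1.36 to 1.99).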

Results

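The series concerns cancer cells that have lost PTDSS2 and their response to inhibition of PTDSS1. PTDSS1 and PTDSS2 are the phosphatidylserine synthases of the endoplasmic reticulum (ER), and PISD converts phosphatidylserine to phosphatidylethanolamine in mitochondria. RNA was measured in HCT116, a colon cancer line, and A375, a melanoma line, as parent cells and as a PTDSS2 knockout clone, after 24 h with vehicle or with 0.1 µM of the PTDSS1 inhibitor DS07551382, in 3 libraries per group. In units of 1e6 counts, library totals ran from 6.21 to 11.69, with a median of 9.20. HCT116 knockout with inhibitor was the shallowest group at 6.89 ± 0.901 (SD, n = 3) and A375 knockout with inhibitor the deepest at 10.5 ± 1.14. Errors of log2 fold changes are standard errors, and each group compared had n = 3.

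PTDSS2 RNA was low in the knockout libraries of both lines. In HCT116 it averaged 35.7 ± 2.35 counts per 1e6 (CPM; SD, n = 3) in parent vehicle, 37.3 ± 2.59 in parent with inhibitor, 6.60 ± 1.24 in knockout vehicle and 5.71 ± 1.29 in knockout with inhibitor. In A375 the values were 23.1 ± 0.952, 22.8 ± 1.65, 0.880 ± 0.141 and 1.63 ± 0.402. Knockout vehicle held 18.5% of the parent level in HCT116 and 3.8% in A375, log2 differences of -2.43 ± 0.11 and -4.71 ± 0.19 (edgeR adjusted p = 2.215e-22 and 2.437e-22). The rise within the A375 knockout, 0.89 ± 0.35 (edgeR adjusted p = 0.04447), lost its call in 11 alternatives, among them DESeq2, limma-voom and the fits without vehicle replicate 1, 2 or 3 or inhibitor replicate 1 or 3.

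**Figure D1:**
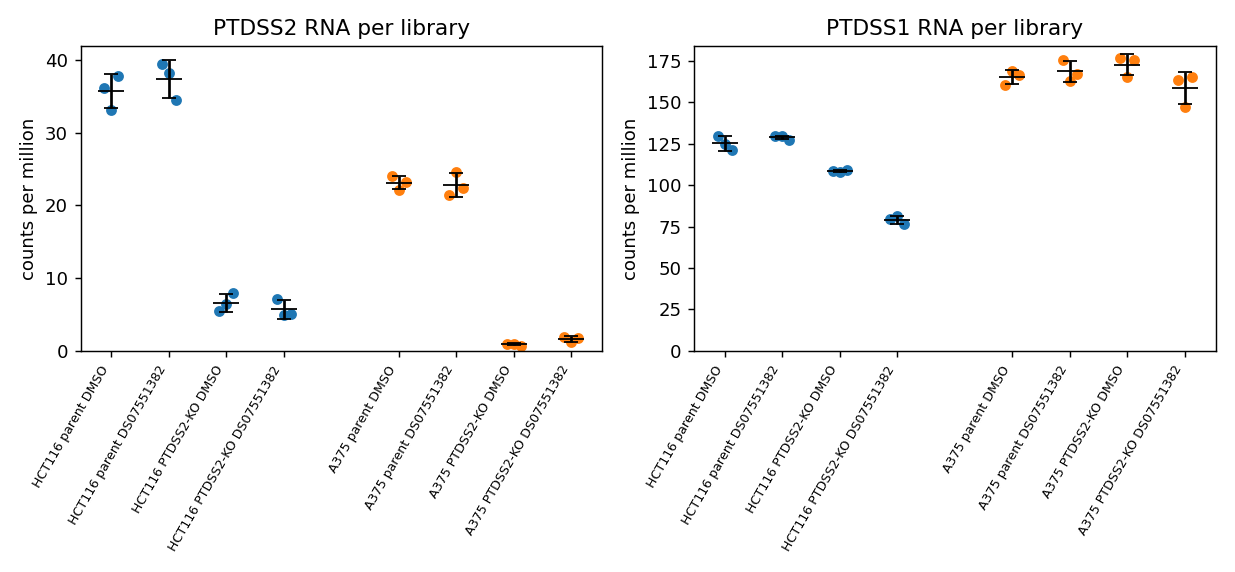
PTDSS2 (left) and PTDSS1 (right) RNA, in CPM on the vertical axis, in each of the 24 libraries by line, genotype and treatment, with points as libraries, dashes as group means and error bars as SD (n = 3). PTDSS2 averaged 6.60 CPM in HCT116 and 0.880 CPM in A375 knockout vehicle, against 35.7 and 23.1 CPM in the parents.

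The parent lines show the inhibitor where PTDSS2 is present. In HCT116 parent cells edgeR called 0 of 13164 genes, with 550 at an unadjusted p under 0.05 against 658 by chance and a smallest adjusted p of 0.8195. DESeq2 called 1 gene and limma-voom 0. PTDSS2, PTDSS1 and PISD had log2 values of 0.07 ± 0.08, 0.04 ± 0.04 and -0.07 ± 0.06. The heat shock and ribosomal protein lists had medians of 0.02 with 0 members called, also when adjusted over the list alone. Both had a camera adjusted p of 0.01469, against adjusted p = 0.6559 and adjusted p = 0.8233 with an estimated correlation.

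In A375 parent cells 12 of 13455 genes changed, 3 up and 9 down, each by less than 2-fold. Sterol genes were prominent among the falls: INSIG1, which retains the sterol sensor in the ER, at -0.42 ± 0.07, and SREBF2, a transcription factor of cholesterol synthesis, at -0.33 ± 0.04. The fatty acid desaturase gene SCD was at -0.22 ± 0.03. The cholesterol exporter gene ABCA1 rose by 0.58 ± 0.09, the serine synthesis gene PSAT1 by 0.15 ± 0.03 and THBS1 by 0.13 ± 0.02. PTDSS2 and PTDSS1 were at -0.02 ± 0.09 and 0.03 ± 0.04. Of 24 cholesterol synthesis genes 4 fell, 10 adjusted over the list alone, and 0 rose, with a median of -0.14 (camera adjusted p = 7.582e-15). Of 13 fatty acid synthesis genes 1 fell, 3 adjusted over the list alone (camera adjusted p = 7.206e-05), and of 38 integrated stress response genes 1 rose, 7 adjusted over the list alone (camera adjusted p = 6.964e-09). These lists held, with adjusted p = 0.0004829, 0.02238 and 0.02238 with an estimated correlation. YAP and SRF targets, with 1 of 17 up and 4 adjusted over the list alone, did not (camera adjusted p = 8.175e-05, and adjusted p = 0.0981 with an estimated correlation). INSIG1, PSAT1 and THBS1 were not called without vehicle replicate 1, and without vehicle replicate 3 there were 8 calls.

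The knockout with inhibitor is the combination in which both synthases are affected. In HCT116 knockout cells 4815 of 13164 genes changed, 2232 up and 2583 down, with 210 up and 39 down at least 2-fold. The integrated stress response, the program of the transcription factors ATF4 and CHOP, rose in 35 of 37 genes, 35 adjusted over the list alone, with 0 down and a median of 0.88 (camera adjusted p = 1.774e-40, and adjusted p = 0.003905 with an estimated correlation). Among its members were the cystine transporter gene SLC7A11 at 2.13 ± 0.05, asparagine synthetase (ASNS) at 1.83 ± 0.04 and PSAT1 at 1.32 ± 0.03. Large rises were also seen in PLPP1, a lipid phosphate phosphatase, at 3.99 ± 0.08, SOCS1 at 3.21 ± 0.20, CHAC1, which degrades glutathione, at 3.07 ± 0.17, FGFBP1 at 2.88 ± 0.15 and DDIT4 at 2.56 ± 0.05. LBH had 0.261 ± 0.132 CPM in knockout vehicle and 26.5 ± 1.87 CPM with inhibitor. Falls were largest in the Wnt antagonist gene DKK1 at -2.43 ± 0.07, THBS1 at -1.80 ± 0.11, AMOTL2 at -1.62 ± 0.07 and CCN1 at -1.37 ± 0.11. PTDSS1 was at -0.45 ± 0.05 (edgeR adjusted p = 2.244e-10), PISD at 0.29 ± 0.06 (edgeR adjusted p = 0.000194) and PTDSS2, not called, at -0.18 ± 0.19.

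Cholesterol and fatty acid synthesis genes were prominent among the rises in the same HCT116 cells. Of 25 cholesterol synthesis genes 21 rose and 0 fell, with INSIG1 at 0.78 ± 0.06 and FDFT1 at 0.63 ± 0.04, and of 13 fatty acid synthesis genes 9 rose and 0 fell, with SREBF1 at 0.73 ± 0.04. Of 17 immediate early genes 14 rose and 0 fell, with NR4A2 at 2.13 ± 0.11 and JUN at 1.21 ± 0.08. Adjusted over the list alone, 22, 9 and 14 rose (camera adjusted p = 1.293e-14, 2.943e-07 and 9.57e-10). Falls were seen in 16 of 19 heat shock genes, with HSPA8 at -0.68 ± 0.03, 23 of 24 ribosome biogenesis genes, 17 of 28 DNA replication genes and 12 of 17 YAP and SRF targets, with AXL at -0.85 ± 0.05. Of these lists only YAP and SRF targets held a rise, of 1 gene. Adjusted over the list alone, 17, 23, 20 and 13 fell, and 1 YAP and SRF target rose (camera adjusted p = 4.278e-15, 1.482e-13, 1.17e-07 and 2.943e-07). These 7 lists held with an estimated correlation. NF-kB and cytokine genes rose in 6 of 12 cases and fell in 2, with the same counts adjusted over the list alone, a median of 0.34, LIF at 1.11 ± 0.05 and NFKBIA at 0.56 ± 0.08 (camera adjusted p = 0.004157, and adjusted p = 0.03417 with an estimated correlation). Of 27 ER chaperone genes 7 rose and 7 fell, also adjusted over the list alone (camera adjusted p = 0.9102), and of 32 phospholipid synthesis genes 9 rose and 7 fell, also adjusted over the list alone (camera adjusted p = 0.7485). Of 20 sphingolipid synthesis genes 2 rose and 6 fell (2 and 7 adjusted over the list alone; camera adjusted p = 0.2517). Of 25 phosphatidylserine transport and flipping genes 8 rose and 5 fell (9 and 5 adjusted over the list alone; camera adjusted p = 0.3921). Colon epithelium markers moved both ways, with 7 of 12 up and 4 down, also adjusted over the list alone, EPCAM at 0.37 ± 0.03 and the keratin gene KRT18 at -0.41 ± 0.03 (camera adjusted p = 0.1708). Mitosis genes fell in 13 of 29 cases and rose in 3 (13 and 4 adjusted over the list alone; camera adjusted p = 0.01328, and adjusted p = 0.1744 with an estimated correlation). NRF2 targets (camera adjusted p = 4.983e-05 to 0.001531) and lysosome and autophagy genes (camera adjusted p = 0.0005464 to 0.004274) were higher in each of the 6 fits with a library left out. Neither list was called with an estimated correlation.

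In A375 knockout cells 5033 of 13455 genes changed, 2506 up and 2527 down, with 142 up and 106 down at least 2-fold. ER chaperone genes rose in 25 of 27 cases, 26 adjusted over the list alone, with 0 down and a median of 0.48 (camera adjusted p = 4.391e-26). HSPA5, which encodes the chaperone BiP, went from 1032 ± 18.8 CPM in vehicle to 1749 ± 9.13 CPM with inhibitor (0.76 ± 0.02), and HERPUD1 rose by 1.17 ± 0.05. SEC24D, a coat gene held by the ER chaperone list, rose by 1.70 ± 0.05. ER to Golgi transport genes rose in 26 of 31 cases and fell in 0 (26 and 1 adjusted over the list alone), with the coat gene COPG1 at 0.78 ± 0.04 (camera adjusted p = 3.156e-19). NF-kB and cytokine genes rose in 16 of 18 cases and fell in 1, with the same counts adjusted over the list alone and a median of 1.23 (camera adjusted p = 5.313e-11). BIRC3, an inhibitor of apoptosis, rose by 2.59 ± 0.11, the chemokine CXCL8 by 2.17 ± 0.08 and RELB by 1.53 ± 0.10, and the complement gene C3 by 2.99 ± 0.18. Of 38 stress response genes 34 rose and 2 fell, with the same counts adjusted over the list alone and SLC7A11 at 1.04 ± 0.03 (camera adjusted p = 7.971e-20). PTDSS1 was at -0.12 ± 0.04 (edgeR adjusted p = 0.01448), a call lost with DESeq2 and without vehicle replicate 1 or 3 or inhibitor replicate 2, and PISD, not called, at -0.09 ± 0.07.

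YAP and SRF targets led the falls in A375 knockout cells. ANKRD1 was at -4.60 ± 0.22, CCN1 at -2.07 ± 0.06, CCN2 at -1.67 ± 0.06 and THBS1 at -1.27 ± 0.02, and 12 of 17 members fell with 0 rising, 12 adjusted over the list alone, at a median of -0.99. CPA4 at -2.17 ± 0.04 and ID3 at -1.69 ± 0.12 also fell. Mitosis genes fell in 28 of 29 cases, with CDC20 at -0.64 ± 0.03, DNA replication genes in 26 of 28, with MCM5 at -0.44 ± 0.04, heat shock genes in 17 of 19 and ribosome biogenesis genes in 22 of 24. Adjusted over the list alone, 28, 26, 17 and 23 fell, and 1 heat shock gene rose. Camera adjusted p for these 5 lists were 9.086e-17, 1.21e-20, 8.847e-15, 8.244e-14 and 4.647e-12. Rises were seen in 18 of 24 cholesterol synthesis genes, with INSIG1 at 0.98 ± 0.06, 11 of 13 fatty acid synthesis genes, 19 of 22 NRF2 targets, with the ferritin gene FTH1 at 0.64 ± 0.02, and 26 of 31 lysosome and autophagy genes, with SQSTM1 at 1.27 ± 0.03. No member of these lists fell, and adjusted over the list alone 18, 12, 20 and 28 rose and 1 cholesterol gene fell (camera adjusted p = 1.278e-08, 2.508e-08, 2.433e-14 and 2.397e-12). Hypoxia and glycolysis genes rose in 19 of 27 cases and fell in 4, also adjusted over the list alone, with VEGFA at 0.61 ± 0.05 (camera adjusted p = 3.341e-05). Phosphatidylserine transport and flipping genes rose in 10 of 25 cases and fell in 1, also adjusted over the list alone, with the flippase gene ATP8B2 at 0.43 ± 0.04 and TMEM30A, a flippase subunit, at 0.21 ± 0.04 (camera adjusted p = 0.02052, and adjusted p = 0.04449 with an estimated correlation). Melanocyte lineage markers rose in 6 of 10 cases and fell in 0 (6 and 1 adjusted over the list alone), with SOX10 at 0.36 ± 0.05 and ERBB3 at 0.51 ± 0.03 (camera adjusted p = 0.01104, and adjusted p = 0.04662 with an estimated correlation). In vehicle this list leaned lower in the knockout than in the parent with each library left out (camera adjusted p = 0.007126 to 0.07814). That fall was not called without parent vehicle replicate 3, nor with an estimated correlation. The fall and the rise share the knockout vehicle libraries, so they are not independent. ERBB3 averaged 335 CPM in parent vehicle, 256 CPM in knockout vehicle and 366 CPM in knockout with inhibitor. MITF averaged 29.1 CPM in knockout vehicle and 25.9 CPM with inhibitor. Of 33 phospholipid synthesis genes 8 rose and 6 fell, also adjusted over the list alone (camera adjusted p = 0.3242). Apart from phospholipid synthesis, the lists given for this comparison held with an estimated correlation.

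**Figure D2:**
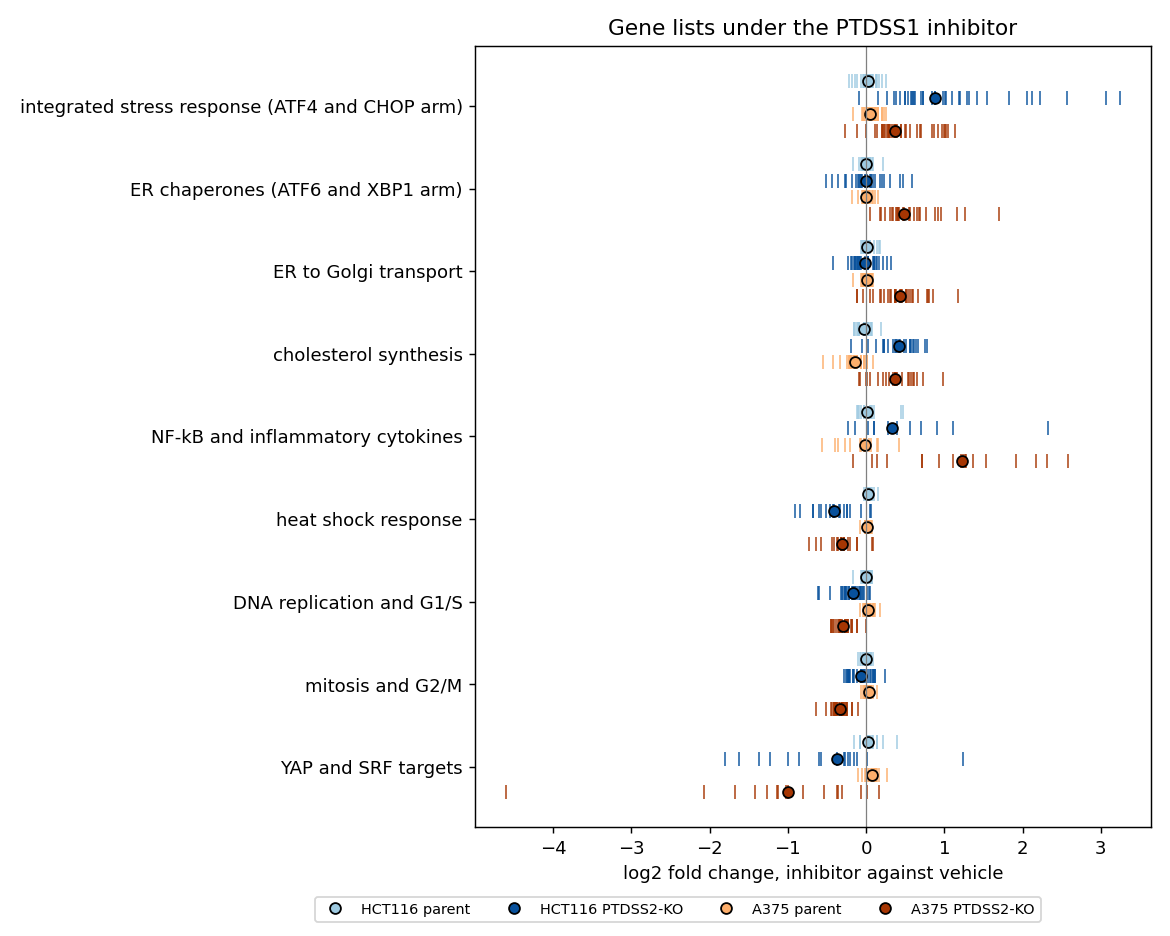
Log2 fold change of inhibitor against vehicle (horizontal axis) for the members of 9 gene lists (rows) in each parent and knockout line (colours), with ticks as genes and circles as list medians. The stress response list had a median of 0.88 in the HCT116 and 0.38 in the A375 knockout, and ER chaperones had a median of 0.48 in the A375 knockout.

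Whether the effect of the inhibitor depended on genotype was tested as the effect in the knockout minus that in the parent. In HCT116 3217 genes differed, 1437 upward and 1780 downward. PLPP1 differed by 3.78 ± 0.20, CHAC1 by 3.29 ± 0.37 and DDIT4 by 2.56 ± 0.10, against -2.47 ± 0.08 for DKK1, -2.02 ± 0.15 for THBS1 and -1.64 ± 0.09 for AMOTL2. Stress response genes differed upward in 31 of 37 cases and downward in 1 (32 and 1 adjusted over the list alone; camera adjusted p = 1.222e-41), cholesterol synthesis genes upward in 18 of 25 (20 adjusted over the list alone; camera adjusted p = 2.621e-15), with SQLE at 0.76 ± 0.07, and heat shock genes downward in 16 of 19 (17 adjusted over the list alone; camera adjusted p = 6.147e-18). These 3 lists held with an estimated correlation. PTDSS1 differed by -0.50 ± 0.06 and PISD by 0.35 ± 0.09. EIF3CL, a near-identical copy of EIF3C, had 0 CPM in some groups, and its call was lost in 15 alternatives, so it is uncertain. DESeq2 called 2061 genes.

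In A375 3615 genes differed, 1752 upward and 1863 downward. BIRC3 differed by 2.98 ± 0.32, CXCL8 by 2.38 ± 0.18 and HSPA5 by 0.79 ± 0.03, against -4.64 ± 0.28 for ANKRD1, -2.48 ± 0.23 for NEXN and -2.18 ± 0.09 for CCN1. INSIG1 differed by 1.40 ± 0.10 and SREBF2 by 0.91 ± 0.06. Upward differences were called in 24 of 27 ER chaperone genes (26 adjusted over the list alone; camera adjusted p = 9.611e-27), 16 of 24 cholesterol synthesis genes (17 adjusted over the list alone; camera adjusted p = 7.105e-12) and 13 of 18 NF-kB genes, with 1 downward (14 and 1 adjusted over the list alone; camera adjusted p = 2.881e-11). Downward differences were called in 27 of 29 mitosis genes (28 adjusted over the list alone; camera adjusted p = 2.625e-21). These 4 lists held with an estimated correlation. DESeq2 called 2397 genes.

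The responses of the knockouts, which share no library, were compared over 12003 genes tested in both lines. Up in both were 778 genes, against 377.8 for independent lists, and down in both 1167, against 492.0. Opposite ways went 358, for which no count for independent lists was computed. Shared rises, HCT116 first, included TRIM2 (1.87 ± 0.05 and 1.07 ± 0.05), BHLHE40 (1.31 ± 0.08 and 1.06 ± 0.09), the neutral amino acid transporter gene SLC1A4 (2.01 ± 0.14 and 1.03 ± 0.05) and DDIT3, which encodes CHOP (2.06 ± 0.12 and 1.01 ± 0.09). Shared falls included CCN1 (-1.37 ± 0.11 and -2.07 ± 0.06), THBS1 (-1.80 ± 0.11 and -1.27 ± 0.02), NMT2 (-1.11 ± 0.08 and -1.13 ± 0.08) and DKK1 (-2.43 ± 0.07 and -0.91 ± 0.03). HSPA1B, at -0.90 ± 0.03 and -0.73 ± 0.04, is nearly identical to HSPA1A and is uncertain. At 2-fold, 15 genes rose and 6 fell in both. Log2 fold changes correlated across genes, which are not independent replicates, with a Pearson r of 0.206 and a Spearman rho of 0.344. DESeq2 gave 1296 genes in both with the same direction, against 1945.

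The inhibitor effect differed between the A375 and HCT116 knockouts for 2736 of 14637 genes, 1520 more positive and 1216 more negative in A375. Fewer genes, 12003, passed the count filter in both lines fitted alone. With a filter at a mean of 5 CPM, 1396 were more positive and 1439 more negative. The effect on ER chaperones was more positive in A375 in 25 of 27 cases, 25 adjusted over the list alone, with HSPA5 at 0.76 ± 0.04, PDIA4 at 0.75 ± 0.04 and DNAJC3 at 0.84 ± 0.06 (camera adjusted p = 6.979e-31). ER to Golgi genes were more positive in 27 of 31, 28 adjusted over the list alone (camera adjusted p = 1.849e-25). Stress response genes were more negative in 27 of 38 cases and more positive in 2 (27 and 3 adjusted over the list alone; camera adjusted p = 4.456e-22), with DDIT4 at -1.85 ± 0.06 and ASNS at -1.44 ± 0.06. Mitosis genes were more negative in 24 of 29, 29 adjusted over the list alone (camera adjusted p = 8.616e-16). NF-kB genes were more positive in 7 of 18 and more negative in 2 (8 and 2 adjusted over the list alone; camera adjusted p = 1.58e-05), with NFKB2 at 0.85 ± 0.07. Some of these NF-kB genes did not pass the count filter in HCT116 fitted alone. These 5 lists held with an estimated correlation. Of 27 phosphatidylserine transport and flipping genes 5 were more positive and 3 more negative (6 and 3 adjusted over the list alone; camera adjusted p = 0.4064). ITGB8 differed by 3.29 ± 0.23, PLPP1 by -3.62 ± 0.15 and PTDSS1 by 0.34 ± 0.07.

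Knockout and parent were compared in vehicle for the state before treatment. With 1 clone per line, clone and genotype cannot be told apart. Over 12003 genes tested in both lines, 148 were higher in both knockouts, against 112.7 for independent lists. Lower in both were 75, against 74.2. More genes, 362, went opposite ways, for which no count for independent lists was computed. Of the genes compared, 1258 were higher and 1340 lower in the HCT116 knockout, and 1075 and 665 in the A375 knockout. Log2 differences of the lines had a Pearson r of 0.0652 and a Spearman rho of -0.0755 across genes. In HCT116 2801 genes differed, 1377 higher and 1424 lower in the knockout. ANXA10 had 16.7 ± 1.07 CPM in the parent and 0.0364 ± 0.0631 CPM in the knockout. The matrix proteoglycan gene VCAN was at -3.85 ± 0.05, NRP1 at -3.68 ± 0.17 and TNS4 at -2.23 ± 0.09, and CEMIP at 2.18 ± 0.14 and the flippase gene ATP10D at 1.64 ± 0.10. PTDSS1 was at -0.21 ± 0.04 (edgeR adjusted p = 0.0002112). Genes activated by p53 were higher in 19 of 28 cases, 22 adjusted over the list alone, and lower in 0, with GDF15 at 0.92 ± 0.06, TP53I3 at 1.05 ± 0.10 and CDKN1A at 0.41 ± 0.04 (camera adjusted p = 1.189e-13, and adjusted p = 0.0007605 with an estimated correlation). Colon epithelium markers were higher in 9 of 12 cases and lower in 1, with the same counts adjusted over the list alone (camera adjusted p = 6.473e-07, and adjusted p = 0.1174 with an estimated correlation). Among the rest, HNF4A averaged 5.77 ± 1.04 CPM in the parent and 0.556 ± 0.0148 CPM in the knockout, and CDX2 17.1 ± 1.26 and 16.8 ± 1.97 CPM. NRF2 targets were also higher in each of the 6 fits with a library left out (camera adjusted p = 1.021e-05 to 0.0001062). Of the 12 lists called, 6 were higher and 6 lower. Ribosome biogenesis and DNA replication genes were lower in each fit with a library left out (camera adjusted p = 1.468e-06 to 8.957e-05 and 0.0001193 to 0.003318). So were cholesterol synthesis and immediate early genes (camera adjusted p = 0.0005973 to 0.004084 and 0.00302 to 0.02861). With an estimated correlation the p53 list was the only list called in this comparison. Knockout vehicle is also the baseline of the inhibitor comparison, in which cholesterol synthesis and immediate early genes rose. DESeq2 called 1563 genes.

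In A375 2115 genes differed in vehicle, 1235 higher and 880 lower in the knockout, while scaling by library size alone gave 787 higher and 1253 lower. IL24 was at 1.94 ± 0.06, ZFPM2 at 1.65 ± 0.12 and PXDN at 1.61 ± 0.06, and BARX1 at -2.99 ± 0.17, KRT81 at -1.92 ± 0.11 and VGF at -1.91 ± 0.10. SPANXB1 at -5.26 ± 0.26, GAGE2A at -2.35 ± 0.19 and SSX2B at -2.04 ± 0.12 belong to families of near-identical copies and are uncertain. YAP and SRF targets were higher in 11 of 17 cases and lower in 1, with the same counts adjusted over the list alone and TPM1 at 0.63 ± 0.03 (camera adjusted p = 2.255e-08, and adjusted p = 0.03251 with an estimated correlation). NRF2 targets were higher in 12 of 22 and lower in 1 (13 and 1 adjusted over the list alone), with NQO1 at 0.42 ± 0.03 (camera adjusted p = 5.85e-08, and adjusted p = 0.02569 with an estimated correlation). In each fit with a library left out, heat shock genes were higher (camera adjusted p = 4.463e-05 to 0.002187). Fatty acid synthesis genes were lower in each (camera adjusted p = 0.0008383 to 0.008213). Neither list was called with an estimated correlation. Knockout vehicle is also the baseline of the inhibitor comparison, in which heat shock genes fell and fatty acid synthesis genes rose. The p53 list had 6 of 27 members higher and 1 lower (7 and 1 adjusted over the list alone; camera adjusted p = 0.1261). DESeq2 called 1205 genes.

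Markers of the tissue of origin were compared with the line names. The epithelial marker EPCAM averaged 296 ± 7.64 CPM in HCT116 parent vehicle and did not pass the count filter in A375, and the melanocyte lineage marker SOX10 averaged 398 ± 5.74 CPM in A375 parent vehicle and did not pass it in HCT116. In knockout vehicle and knockout with inhibitor EPCAM averaged 349 ± 9.58 and 450.0 ± 9.23 CPM in HCT116, and SOX10 334 ± 18.6 and 428 ± 22.4 CPM in A375 (SD, n = 3). Not every listed marker separated the lines this clearly. In parent vehicle of HCT116 and A375, the melanocyte list member RAB38 averaged 13.3 and 19.8 CPM, and the colon list member KRT18 722 and 251 CPM. Some markers went the other way at low counts. The melanocyte list member GPM6B averaged 0.893 and 0.283 CPM. PMEL, also of that list, averaged 2.78 CPM in HCT116 and did not pass the filter in A375. The colon list member TFF3 averaged 1.59 CPM in A375 and did not pass it in HCT116.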

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

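The tests of p53 targets between the lines and of the single clone were chosen after the result was seen, as were the corrections for GC content, gene length and depth.

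The inhibitor effect differed between genotypes, by a test of the difference itself, for 3217 genes in HCT116 and 3615 in A375, and between the knockouts of the lines for 2736. Lists that held in these tests with an estimated correlation had, in HCT116, median differences of 0.90 for the stress response, 0.68 for immediate early genes, 0.47 for cholesterol synthesis, 0.32 for fatty acid synthesis, -0.21 for DNA replication, -0.26 for ribosome biogenesis, -0.45 for heat shock and -0.45 for YAP and SRF targets. In A375 the medians were 1.26 for NF-kB, 0.56 for ER chaperones, 0.51 for cholesterol synthesis, 0.43 for ER to Golgi transport, 0.41 for fatty acid synthesis, 0.41 for NRF2 targets, 0.30 for the stress response, 0.29 for lysosome and autophagy and 0.13 for hypoxia. They were -0.24 for ribosome biogenesis, -0.32 for DNA replication, -0.32 for heat shock, -0.37 for mitosis and -0.97 for YAP and SRF targets. Between the knockouts, A375 minus HCT116, they were 0.67 for NF-kB, 0.51 for ER chaperones, 0.48 for ER to Golgi transport, 0.21 for NRF2 targets, 0.15 for lysosome and autophagy, -0.26 for mitosis, -0.30 for immediate early genes and -0.42 for the stress response.

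The 10 splits of 3 against 3 libraries are too few for a share under 0.05. The labels gave 4815 genes in the HCT116 knockout and the highest other split 0, in the A375 knockout 5033 and 0, for genotype in HCT116 2801 and 0, for genotype in A375 2115 and 2, in A375 parent cells 12 and 1, and in HCT116 parent cells 0 and 1. As many genes as the labels gave came from 1 of 10 splits in each of these, except HCT116 parent cells with 10 of 10. For the differences of effects, 100 of 200 splits were fitted, with the real split included. At least 3217 genes came from 4 of 100 splits in HCT116 (highest other 3405), at least 3615 from 1 of 100 in A375 (highest other 3462), and at least 2736 from 2 of 100 between the lines (highest other 5436). These shares concern the grouping as a whole and do not exclude chance. In HCT116 and A375, 10 of the other splits kept the treatment labels of the knockout apart whatever the parent labels were, and gave 2845 to 3405 and 2996 to 3462 genes. Between the lines, 10 kept those of the A375 knockout apart and gave 1021 to 5436. The shares therefore rest on the response of the knockout and do not test the difference of effects, and these splits alone are too few for a share under 0.05. The split with 5436 genes kept them apart in both lines but exchanged in 1 of them, so that the responses add up.

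ER chaperone genes rose in the A375 knockout, and by the test of the difference in inhibitor effect their change was more positive there than in the HCT116 knockout. Lower depth in HCT116 is argued against, since 25 of 27 members rose in A375 with the knockout libraries thinned to 6211624 counts. A baseline higher in HCT116 by as much as the A375 rise of 0.48 is argued against by a median difference of -0.23 in knockout vehicle (bootstrap interval over genes -0.39 to 0.34). A smaller difference in baseline stays open. GC content and length as the whole cause are argued against by a camera adjusted p of 1.773e-30 after their trends were removed. A difference between the lines and a difference between their single clones both stay open and were not tested apart.

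Of 24 cholesterol synthesis genes 4 fell in A375 parent cells (10 adjusted over the list alone), with a median of -0.14, and 18 rose in the knockout. A single deciding library is argued against by a highest camera adjusted p of 3.63e-11 with each of the 6 parent libraries left out. GC content and length are argued against by 1.044e-16 after trend removal, and depth by 3.215e-14 with the parent libraries thinned to a common total. Whether the pattern depends on PTDSS2 was not tested, because 1 clone leaves other differences from the parent open.

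Genes activated by p53 were higher in the HCT116 knockout clone in vehicle. A single deciding library is argued against by a highest camera adjusted p of 5.245e-13, and GC content and length by 2.111e-13. The change from parent to knockout clone was not alike in the lines. Its median difference, A375 minus HCT116, was -0.17 (camera adjusted p = 8.463e-05, and adjusted p = 0.003505 with an estimated correlation), with 10 of 29 members lower and 0 higher. Whether PTDSS2 loss itself acts equally in both lines cannot be decided from this, because each line had 1 clone. A property of the clone cannot be told apart from an effect of the knockout in HCT116, because 1 clone was sequenced.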

How the results depend on the processing

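The corrections for GC content, gene length and depth were chosen after seeing the data. Under the alternatives 15993 values of named genes kept direction and side of the threshold, 411 lost the call and 10 gained it, and for the lists already called 1518 values kept the call and 138 lost it. Lists gaining a call are not in these counts. DESeq2 gave 1563 genes for genotype in HCT116 (main 2801) and 1205 in A375 (2115), 2061 for the difference of effects in HCT116 (3217) and 2397 in A375 (3615), and 1296 shared genes (1945), and the cause was not tested. Requiring 2-fold left 21 shared genes by construction. In HCT116 parent cells DESeq2, the 6 libraries alone and thinning each gave 1 gene in place of 0. Leaving out a library gave 0 to 2 genes there (1 without inhibitor replicate 1, 2 without inhibitor replicate 3), 3997 to 4326 in the HCT116 knockout, 2217 to 2451 for its genotype, 2695 to 3014 for its difference of effects, 8 to 12 in A375 parent cells, 4347 to 4582 in the A375 knockout, 1553 to 1753 for its genotype, 3198 to 3450 for its difference of effects, 2399 to 2565 between the lines and 1689 to 1810 shared genes. With an estimated correlation the lists called went from 2 to 0 in HCT116 parent cells, 16 to 9 in its knockout, 12 to 1 for its genotype, 16 to 8 for its difference of effects, 8 to 3 in A375 parent cells, 9 to 2 for A375 genotype and 13 to 8 between the lines. The fry test gave 0 in HCT116 parent cells, 4 in A375 parent cells, 23 for A375 genotype and 23 between the lines, library size alone 4 in A375 parent cells and 5 for A375 genotype, and trend removal 0 in HCT116 parent cells; the cause was not tested. Leaving out a library gave 0 to 5 lists in HCT116 parent cells (1 without vehicle replicate 1, 5 without vehicle replicate 2, 0 without vehicle replicate 3, 1 without inhibitor replicate 2), 4 to 9 in A375 parent cells (4 without vehicle replicate 1, 4 and 5 without inhibitor replicates 1 and 2) and 5 to 11 for A375 genotype (5 without parent vehicle replicate 1). PTDSS2 in knockout vehicle was 18.2% of parent by TPM in HCT116 and 3.69% in A375. With libraries thinned to the smallest total of the line, and fewer genes tested, there were 4364 genes in the HCT116 knockout (4815), 2191 for its genotype (2801) and 4581 in the A375 knockout (5033).

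The replicate numbers did not pair the samples: correlations of same-numbered deviations from the group means ran from -0.103 to 0.111, and in no comparison did every sample correlate best with its own number. A replicate block gave 4911 genes in the HCT116 knockout, 5051 in the A375 knockout, 2906 and 2146 for genotype, and moved no count of calls by over 1.5 times.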

Other observations

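Apoptosis regulators moved both ways in the knockouts with inhibitor. BCL2L1, which encodes the survival protein BCL-XL, was at -0.72 ± 0.04 in HCT116 and -0.65 ± 0.05 in A375, while BCL2L11, which encodes the death-promoting protein BIM, rose by 0.49 ± 0.08 in HCT116 and XIAP, a caspase inhibitor, by 0.31 ± 0.05 in A375. Of 21 members 7 rose and 7 fell in HCT116 (8 and 7 adjusted over the list alone), and of 20 members 8 rose and 1 fell in A375 (8 and 2 adjusted over the list alone), with camera adjusted p of 0.9102 and 0.1677. The cyclin D1 gene CCND1 was at -0.66 ± 0.03 in HCT116 and -0.55 ± 0.03 in A375.

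The tests of synthetase genes were chosen after the rise of the stress response list, which holds 7 of the 12 genes concerned, had been seen. In the HCT116 knockout the 12 cytosolic aminoacyl-tRNA synthetase genes known to depend on ATF4 had a median log2 change of 0.43, against -0.20 for 8 others, and in A375 0.22 against -0.10. An exact one-sided permutation test of the difference of medians over genes gave p = 0.000445 in each line, the smallest it can give. The 5 genes outside the stress response list had medians of 0.28 and 0.12, with an exact permutation p of 0.00777 in each line. The pattern is consistent with ATF4 separating the synthetases that rose, as a hypothesis, and genes are not independent replicates.

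ID2 in HCT116 and ID3 in A375 were among the largest falls, and lower BMP signalling in the knockouts was a candidate explanation. It was tested on BMP targets other than ID2, ID3 and SMAD6. The 7 tested in HCT116 had a median of 0.12, with 2 up and 1 down, and the 11 tested in A375 a median of 0.06, with 3 up and 3 down. Camera gave an unadjusted p of 0.3929 in HCT116 and 0.8804 in A375, so a joint fall of these targets was not found.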
